A study of Mus musculus with 24 samples.

How the data were processed

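Poly(A) RNA was sequenced from 24 mouse muscle samples taken on day 7 after ligation of the femoral artery in 1 hindlimb. Per the labels, the samples form 4 groups of 6: normoxic adductor and ischemic gastrocnemius muscle, each from control mice and from mice with type 2 diabetes. The labels do not say how diabetes was produced, nor whether an adductor and a gastrocnemius sample with the same number came from the same animal. Where they give no animal numbers, the p-values measure the spread between these samples.

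Per the file headers, the deposited values are RPKM (reads per kilobase of exon per M reads of the library total named in each header), computed by the authors with HOMER over the exons of each RefSeq transcript of mouse build mm9. TopHat, HOMER and mm9 are named in the submitters' processing notes, with no versions or settings. The header command shows no strand option, so reads of overlapping and antisense genes could not be told apart, and no header or label says how reads matching several places were treated. The table held 33022 transcripts under 24016 gene symbols, and each of its 24 columns matched the title of 1 sample. Each deposited RPKM multiplied by transcript length and library total gave a whole number of reads within 0.01 for 99.97% of the values above 0. Library totals in the headers ran from 7.13 to 15.6 M reads, and 14668 to 18081 genes were above 0 in a library. A floor of 3 reads for a transcript of 1 kb corresponded to an RPKM of 0.192 in the deepest library and 0.421 in the shallowest. Such floors cover counting error only. RPKM shares 1 total among all genes, so a few very abundant transcripts that fall in a group raise the values of all others.

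For each symbol the transcript with the highest mean RPKM was kept. Genes with an RPKM of at least 1 in at least 6 libraries were tested, which left 12382. A pseudocount of 0.5 was added and the log2 values were fitted in limma 3.58.1 under R 4.3.3 with 4 group means and an intensity trend in the variance. The 5 contrasts were diabetic minus control in each muscle, the difference between those effects (gastrocnemius minus adductor), and gastrocnemius minus adductor within each mouse group. P-values were adjusted by the Benjamini-Hochberg method within a contrast and called at 0.05. Fold changes are given as log2 differences ± standard error from limma, and RPKM as mean ± SD with n = 6 per group. For 32 gene lists fixed before the data were examined, limma's camera compared each list with all other tested genes at a preset correlation of 0.01, with adjustment over the lists, and again with the correlation estimated from the data. Members of a list were also counted after the p-values were adjusted over the list alone. The tests, the lists, the alternatives and the naming rule were set before the data were examined. The rule named, for the diabetes contrasts and the control muscle contrast, the 6 highest and 6 lowest called genes with a mean of at least 2 RPKM in the higher group (if fewer than 3 passed, the 6 smallest p-values), up to 4 members of each list with 3 or more called members or a camera adjusted p under 0.05, and always a set of genes fixed in advance, among them Vegfa, Kdr, Flt1, Igf2, Apob, Slc2a4, Pdk4, Ucp3 and Adipoq. For the difference of effects and the diabetic muscle contrast it named the 5 smallest p-values.

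On simulated normal log2 values with the real mean and spread of each gene and no sets of libraries, 57 of 100 genes changed by a log2 difference of 1 and 94 of 100 changed by 2 were called in the adductor contrast over 12382 genes. In the gastrocnemius contrast the figures were 57 and 90, in the difference of effects 24 and 75, in the control muscle contrast 58 and 88, and in the diabetic muscle contrast 50 and 95. Between 6 and 9 unchanged genes were called in each. Genes of both sizes were changed in the same simulation, and the noise was independent between genes. Fewer true changes make the adjusted threshold stricter, so recovery in the real diabetes contrasts may be lower. The recovered reads of the 60 pairs of libraries within groups differed with a chi-square per degree of freedom of 10.6 to 324, so no pair was the same library sequenced again. This does not show that the libraries come from different animals.

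The libraries fell into sets that the labels do not name, told apart after the data were seen by the level of Gapdh. The first set held 14 libraries (control 1 to 3 and diabetic 1 to 4 of both muscles) and the second set 10 (control 4 to 6 and diabetic 5 and 6). Each diabetes contrast was therefore refitted with a term for the set in each muscle, and within each set alone. Same-numbered samples of the muscles of 1 mouse group deviated together from their group means, with r of 0.25 to 0.74 across genes over 12 pairs, though within the sets r ran from -0.09 to 0.63. All 12 pairs matched in their pattern of sex-linked genes, but so did all same-numbered control and diabetic samples, so this match does not tell animals apart. By the criterion fixed for this check (every r over 0.1) the numbers pair the muscles, but the sets contribute to these correlations and the labels do not state the pairing. Between control and diabetic samples r ran from -0.66 to 0.82, so these numbers were not treated as pairs.

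Alternatives were other pseudocounts, filters and variance models, median-of-ratios and quantile scaling, fits of only the groups compared, sample weights, summed transcripts, the replicate number as a block and the omission of each library in turn. After the data were seen, voom on the recovered reads, terms for sex-linked expression and the omission of a pair of libraries were added. The share of each gene's 31-base words found in another gene came from the transcripts of GENCODE M21 and was used as a measure of shared sequence. The share was matched by gene symbol. Apob was left out of the tests because it reached at most 0.0546 RPKM.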

Results

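Gene expression was measured by poly(A) RNA sequencing in hindlimb muscles of mice 7 days after ligation of the femoral artery, an operation that diverts flow to collateral arteries of the upper leg and leaves the calf ischemic. The normoxic adductor, where the labels place growth of arterioles, and the ischemic gastrocnemius, where they place growth of capillaries, were sampled from control mice and from mice with type 2 diabetes, with 6 libraries in each of 4 groups. Depth ran from 7.13 to 15.6 M reads per library. The first principal component of the 12382 tested genes held 60.0% of the variance and separated the muscles, and the second, with 24.4%, separated sets of libraries within every group.

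These sets were not named in the labels. The labels do name more than 1 model of sequencing instrument, and whether the sets differ in instrument was not tested. In 14 libraries Gapdh, a glycolytic enzyme often used as a reference gene, lay between 677 and 1757 RPKM, and in the other 10 between 0.365 and 13.7 RPKM. The first set (control 1 to 3 and diabetic 1 to 4) had 12.0 to 15.6 M reads and the second set (control 4 to 6 and diabetic 5 and 6) 7.13 to 11.8 M. Across genes, libraries of 1 group correlated at 0.875 to 0.984 within a set and at 0.806 to 0.916 between sets. Each set held both mouse groups in unequal shares. For the diabetes contrasts within-set values therefore stand beside the pooled ones of called genes and of lists that passed. Within the second set Gapdh itself parted the mouse groups, at 0.365 to 0.831 RPKM in control and 3.71 to 13.7 RPKM in diabetic libraries. What parts the sets may thus also run with diabetes inside the second set, and second-set values and set terms may not remove it. Gapdh is also a member of the glycolysis list.

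**Figure D1:**
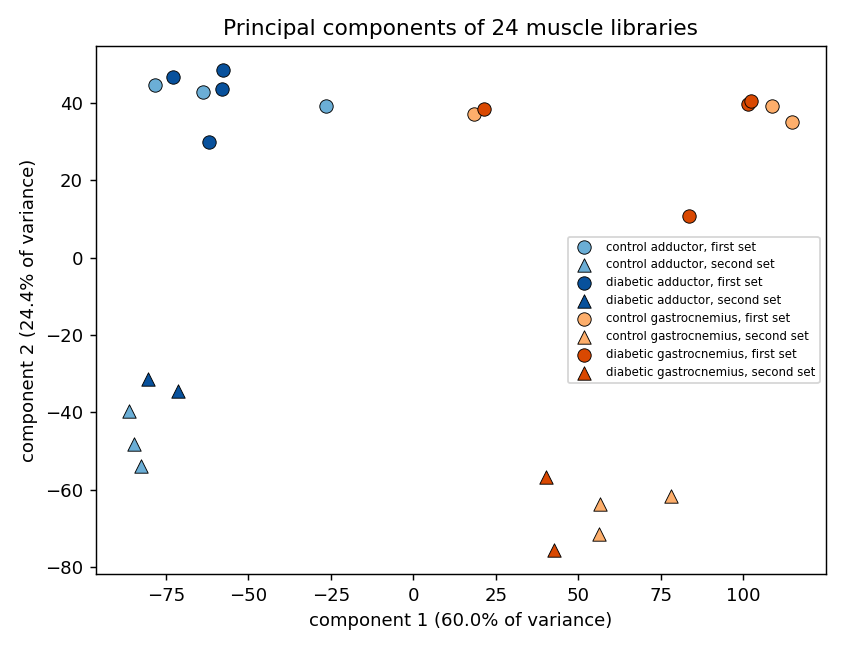
Principal components of the log2 RPKM of 12382 genes in 24 libraries, with the first component on the horizontal axis and the second on the vertical axis, each labelled with its share of the variance. Colours give the group and symbols the set: the first component (60.0%) parts adductor from gastrocnemius and the second (24.4%) parts the sets told apart by Gapdh.

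The first comparison asked which transcripts differed between diabetic and control mice in the adductor. Nnt, which encodes the mitochondrial nicotinamide nucleotide transhydrogenase, rose from 5.57 ± 1.01 to 35.7 ± 9.87 RPKM (SD, n = 6), a log2 difference of 2.54 ± 0.23. Serpina3n, a secreted serine protease inhibitor of the acute phase, rose from 3.13 ± 1.54 to 18.4 ± 7.55 RPKM. Abcg1, a cholesterol efflux transporter, rose from 0.865 ± 0.609 to 4.05 ± 1.87 RPKM, and the lipocalin Apod rose from 17.5 ± 5.03 to 39.3 ± 9.11 RPKM. By limma 4 genes were called higher and 0 lower among the 12382 tested, with 339 at an unadjusted p under 0.05, and voom also called 4.

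The limma adjusted p was 7.8e-07 for Nnt, 0.033 for Serpina3n (2.40 ± 0.41), 0.037 for Apod (1.16 ± 0.21) and 0.046 for Abcg1 (1.74 ± 0.32). All 6 diabetic libraries exceeded every control library for Nnt, Serpina3n and Apod, and 5 of 6 did for Abcg1. Within the first and second set the log2 differences were 2.35 and 2.82 for Nnt, 2.57 and 2.07 for Serpina3n, 1.35 and 2.27 for Abcg1, and 1.12 and 1.18 for Apod. With terms for the set, 5 genes were called higher and 0 lower. In the first set alone limma called 1 higher, and in the second set alone 12 higher and 2 lower. Of those 14 genes, 9 shared at least 20% of their 31-base words with another gene, compared with 8.77% of all tested genes. When each of the 24 libraries was left out in turn, Nnt passed in all 24 fits, Serpina3n in 17, Apod in 12 and Abcg1 in 7, and Abcg1 and Apod also missed the threshold under some of the other settings, such as adjusted p of 0.19 for Abcg1 with a pseudocount of 1 and 0.14 for Apod with median-of-ratios scaling. In the mm9 coordinates of the deposited table, Nnt (NR_003544) spans chromosome 13 from 120124334 to 120197945 on the minus strand, Serpina3n (NM_009252) chromosome 12 from 105644918 to 105652539 on the plus strand, Abcg1 (NM_009593) chromosome 17 from 31194639 to 31254926 on the plus strand, and Apod (NM_007470) chromosome 16 from 31296278 to 31314894 on the minus strand. The values cover all annotated exons of each transcript.

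**Figure D2:**
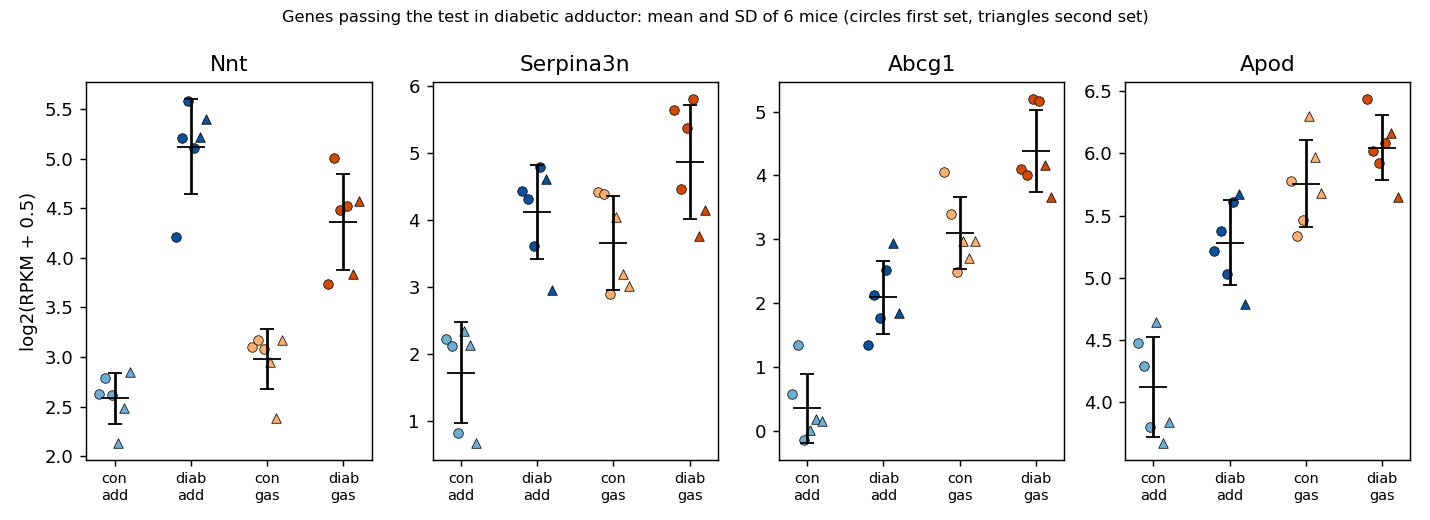
RPKM of Nnt, Serpina3n, Abcg1 and Apod in each of the 24 libraries by group, with the mean and SD of each group as bars. Circles mark libraries of the first set and triangles those of the second. Diabetic adductor libraries lie above all control adductor libraries except 1 for Abcg1. Before the log2 step the adductor means of Nnt were 35.7 RPKM in diabetic and 5.57 RPKM in control mice.

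At the preset correlation 10 gene lists passed in adductor and 14 in gastrocnemius. Other groupings of the same libraries gave a median of 8 and 9 lists. Among the gene lists, transcripts of red blood cells were lowest in the diabetic adductor. The 6 erythroid markers had a median log2 difference of -1.48 (camera adjusted p = 1.1e-11), with 0 of 6 called over all genes and 4 lower when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.085). Hbb-b1, a beta globin gene, had 146 ± 154 RPKM in control and 43.7 ± 26.8 RPKM in diabetic muscle, the control mean being raised by control adductor 4 with 455 RPKM against 47.9 to 119.5 in the other 5, and Alas2, the erythroid enzyme of heme synthesis, had 2.05 ± 1.32 and 0.631 ± 0.346 RPKM (SD, n = 6). Globin genes are near-identical copies that share reads, so the members are not independent. The within-set medians were -1.22 and -1.29.

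Contractile and metabolic lists differed as well at the preset correlation. All 10 slow-fibre contractile genes had positive values (median 0.65, adjusted p = 1.2e-06), with 1 higher when adjusted over the list alone, and within-set medians of 0.41 and 1.01. The adjusted p was 0.085 with an estimated correlation. The calcium pump gene Atp2a2 had 38.6 ± 22.6 RPKM in control and 75.3 ± 22.7 RPKM in diabetic adductor, and Myl2, a slow myosin light chain, had 59.4 ± 34.0 and 150 ± 41.1 RPKM (SD, n = 6). The fast-fibre list had a median of -0.36 (adjusted p = 0.02; within the sets -0.25 and -0.09), and its members Mylpf and Myl1 had log2 differences of -0.67 ± 0.42 and -0.50 ± 0.34. Among 40 oxidative phosphorylation genes only 1 was positive (median -0.29, adjusted p = 2.8e-08; within the sets -0.15 and -0.12). The glycolysis list had a median of -0.30 (adjusted p = 1.4e-05; within the sets -0.45 and -0.06), with Ldha, lactate dehydrogenase A, at -0.69 ± 0.30. The fatty acid oxidation list had a median of 0.27 (adjusted p = 0.015; within the sets 0.28 and 0.34), with the fatty acid binding protein Fabp3 at 118 ± 33.7 in control and 223 ± 87.0 RPKM in diabetic muscle. For the fast-fibre, oxidative phosphorylation, glycolysis and fatty acid oxidation lists the adjusted p was 0.68 with an estimated correlation, and no member passed over all genes.

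Connective tissue lists changed direction between the sets. The 23 extracellular matrix genes had a pooled median of -0.20 (adjusted p = 0.0064) but -0.80 in the first and 0.38 in the second set, and the 10 fibroblast markers had -0.19 (adjusted p = 0.018) but -0.60 and 0.40. The first-set values rest on 3 control libraries, of which control adductor 2 had 98.2 RPKM of the matrix gene Bgn against 42.2 and 22.4 in the others. Interferon-stimulated genes had a median of 0.26 with 18 of 19 positive (adjusted p = 0.0024), and 0.07 and 0.43 within the sets. Immediate early genes had a median of -0.18 (adjusted p = 0.026), and -0.18 and 0.03 within the sets. All 4 lists had an adjusted p of 0.68 with an estimated correlation. With median-of-ratios scaling the fast-fibre (adjusted p = 0.094), fatty acid oxidation (0.094) and immediate early (0.081) lists did not pass, and with terms for the set the immediate early list did not (0.072). Markers of endothelial cells (median 0.14, adjusted p = 0.99), smooth muscle cells (0.02, adjusted p = 0.18), macrophages (0.17, adjusted p = 0.20) and adipocytes (-0.23, adjusted p = 0.11) did not pass, nor did the angiogenic ligands and receptors (-0.05, adjusted p = 0.25) or the hypoxia-induced genes (0.03, adjusted p = 0.63). Some of these pooled values hide opposite directions in the sets: endothelial markers had -0.17 (adjusted p = 0.013) in the first and 0.36 (adjusted p = 0.012) in the second set, and muscle atrophy genes, with a pooled median of 0.15 (adjusted p = 0.17), had 0.57 (adjusted p = 4.8e-07) and -0.39 (adjusted p = 2.1e-05). Smooth muscle markers had -0.29 (adjusted p = 0.0016) and 0.31 (0.13), macrophage markers -0.36 (0.065) and 0.64 (2.6e-07), and the angiogenic list -0.23 (0.0033) and 0.19 (0.23). Of the genes examined in any case, the log2 differences were -0.32 ± 0.30 for the growth factor gene Vegfa, 0.33 ± 0.42 for its receptor gene Kdr, 0.10 ± 0.32 for Flt1, -0.53 ± 0.45 for Igf2 (-1.26 in the first set, which holds control adductor 2 with 119.8 RPKM, and 0.20 in the second), -0.29 ± 0.39 for the glucose transporter gene Slc2a4, -0.46 ± 0.71 for Pdk4, -0.49 ± 0.55 for Ucp3 and 0.24 ± 0.58 for Adipoq, and none passed.

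The same comparison in the ischemic gastrocnemius gave Nnt as its 1 called gene. It rose from 7.50 ± 1.45 to 20.9 ± 6.92 RPKM (SD, n = 6), a log2 difference of 1.38 ± 0.23, with all 6 diabetic libraries above every control library. The next genes by p-value did not pass, although Casp4 did with a pseudocount of 1 (adjusted p = 0.039) and with quantile normalization (0.017). They were Casp4, an inflammatory caspase (2.80 ± 0.926 and 0.876 ± 0.251 RPKM, log2 difference -1.23 ± 0.23), Apoc1, an apolipoprotein (4.07 ± 2.35 and 16.1 ± 6.04 RPKM, 1.95 ± 0.43), the transcription factor subunit Snapc1 (-0.78 ± 0.17), Alas2 (-1.32 ± 0.29) and the lectin receptor gene Clec4d (-1.54 ± 0.37).

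The limma adjusted p was 0.036 for Nnt, 0.10 for Casp4, 0.66 for Clec4d, and 0.35 for Snapc1, Apoc1 and Alas2. With terms for the set the adjusted p of Nnt was 0.056 and limma called 0 genes, with 537 at an unadjusted p under 0.05. Voom called 1 gene with these terms and 1 without. Within the sets the log2 differences of Nnt were 1.32 and 1.37. The first set alone gave 0 calls with limma and 93 unadjusted, and the second set alone gave 20 genes higher and 7 lower, of which 17 shared at least 20% of their 31-base words with another gene. Nnt passed in 7 of 24 fits with 1 library left out.

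Erythroid markers were again the lowest list, with a median of -2.20 over 6 genes (camera adjusted p = 2.1e-21; 0.009 with an estimated correlation) and 6 of 6 lower when adjusted over the list alone, although 0 passed over all genes. Hbb-b1 had 127 ± 88.9 RPKM in control and 28.1 ± 23.2 RPKM in diabetic muscle (SD, n = 6). The within-set medians were -2.21 and -1.31, and with terms for the set the list's adjusted p was 0.068 with an estimated correlation.

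Genes of cholesterol synthesis and uptake were lower in the diabetic gastrocnemius, with 0 of 17 positive (median -0.41, adjusted p = 5.0e-11), 4 lower when adjusted over the list alone and within-set medians of -0.38 and -0.68. The adjusted p was 0.13 with an estimated correlation. Sqle, squalene epoxidase, had 2.91 ± 2.08 RPKM in control and 1.03 ± 0.557 RPKM in diabetic muscle, and Cyp51, lanosterol demethylase, had 3.60 ± 1.82 and 1.60 ± 0.254 RPKM (SD, n = 6). Several lists of lipid storage and use were higher. Of 10 adipocyte markers 9 were positive (median 0.64, adjusted p = 1.9e-08; within the sets 0.52 and 0.45; adjusted p = 0.17 with an estimated correlation), with hormone-sensitive lipase Lipe at 0.74 ± 0.27. Fatty acid oxidation genes had a median of 0.16 with 19 of 23 positive (adjusted p = 1.9e-08; within the sets 0.19 and 0.26; adjusted p = 0.20 with an estimated correlation). Lipogenic genes had a median of 0.21 (adjusted p = 0.0037; within the sets -0.15 and 0.19; adjusted p = 0.51 with an estimated correlation), with the desaturase gene Scd1 at 1.41 ± 0.51 and the lipogenic transcription factor Srebf1 at 0.88 ± 0.33. None of these members passed over all genes.

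Fibre lists were higher as well: the slow-fibre list had a median of 0.16 with 10 of 10 positive (adjusted p = 7.5e-05; within the sets 0.19 and 0.52; adjusted p = 0.17 with an estimated correlation) and the fast-fibre list 0.14 with 12 of 14 positive (adjusted p = 0.007; within the sets 0.21 and 0.48). Extracellular matrix genes had a median of -0.46 with 1 of 23 positive (adjusted p = 0.00035; within the sets -0.48 and -0.71), for example the tenascin gene Tnc at -1.02 ± 0.64 and the lysyl oxidase gene Lox at -0.69 ± 0.50. Cell cycle genes had -0.27 (adjusted p = 0.01; within the sets -0.32 and -0.35). Immediate early genes had -0.36 (adjusted p = 0.00035; within the sets -0.42 and -0.19), and neutrophil markers -0.92 (adjusted p = 0.027; within the sets -0.22 and -1.33). Interferon-stimulated genes had 0.13 (adjusted p = 7.5e-05) but 0.44 and -0.31 within the sets, and the glycolysis list 0.12 (adjusted p = 0.049) but -0.04 and 0.26. Endoplasmic reticulum stress genes had -0.25 (adjusted p = 0.049; within the sets -0.16 and -0.28). With terms for the set the neutrophil (adjusted p = 0.078), lipogenic (0.061) and endoplasmic reticulum (0.44) lists did not pass, the last passing in neither set alone, and with median-of-ratios scaling the glycolysis list did not (0.13). With an estimated correlation the adjusted p was 0.41 for neutrophil markers and immediate early genes, 0.54 for interferon-stimulated genes, 0.65 for cell cycle genes and 0.59 for the fast-fibre, matrix, glycolysis and endoplasmic reticulum lists. Markers of endothelial cells (-0.15, adjusted p = 0.25) and macrophages (0.01, adjusted p = 0.13) did not pass, nor did the angiogenic ligands and receptors (-0.15, adjusted p = 0.11) or the hypoxia-induced genes (-0.12, adjusted p = 0.067), although the latter passed downward with median-of-ratios scaling (adjusted p = 0.039) and with terms for the set (0.029). For the hypoxia list an estimated correlation gave an adjusted p of 0.51, and 0.32 with terms for the set as well. The log2 differences were 0.29 ± 0.30 for Vegfa, -0.15 ± 0.42 for Kdr, 0.16 ± 0.32 for Flt1, 0.03 ± 0.45 for Igf2, 0.39 ± 0.39 for Slc2a4, -0.09 ± 0.71 for Pdk4, -0.07 ± 0.55 for Ucp3 and 0.99 ± 0.58 for Adipoq, and none passed.

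**Figure D3:**
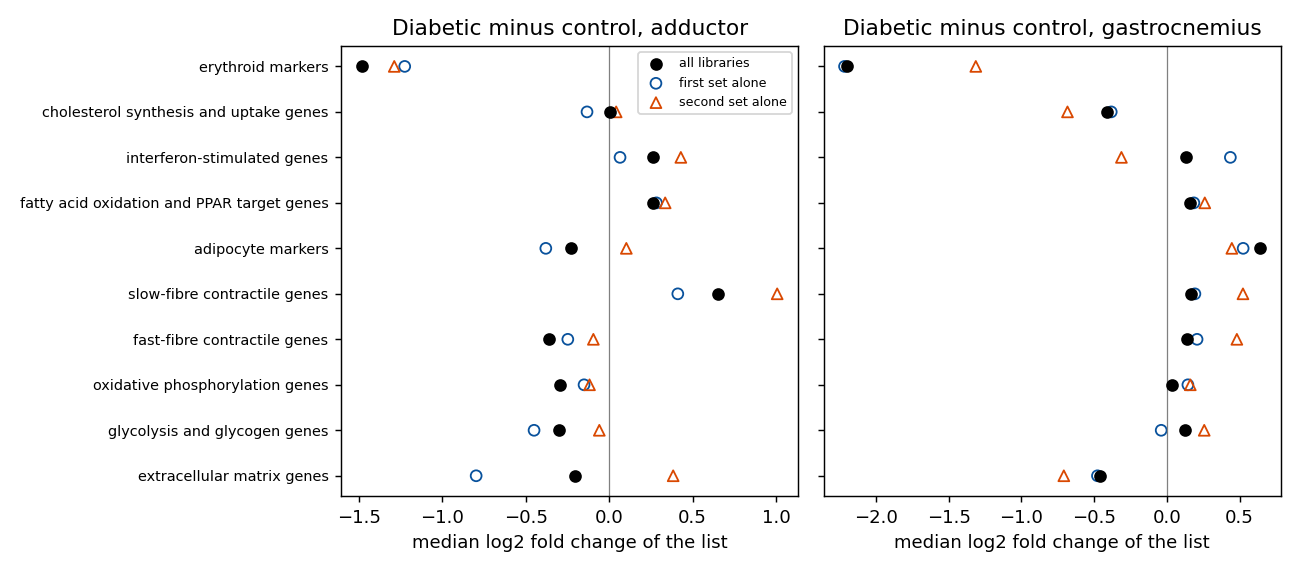
Median log2 difference, diabetic minus control, of selected gene lists in the adductor and in the gastrocnemius, for all libraries and for each set of libraries alone. Other tested lists, such as the endothelial, macrophage, angiogenic and hypoxia lists, are not shown. Erythroid markers lie lowest in both muscles (-1.48 and -2.20), and the extracellular matrix list of the adductor has -0.80 in the first and 0.38 in the second set.

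Whether the diabetes effect differed between the muscles was tested as the difference of both effects, gastrocnemius minus adductor. The genes with the smallest p-values did not pass. Igfn1, an immunoglobulin-like protein gene of muscle, had 11.1 ± 6.20 and 49.2 ± 34.8 RPKM in control and diabetic adductor but 10.4 ± 3.34 and 7.51 ± 2.51 RPKM in gastrocnemius (SD, n = 6). Figf, a vascular endothelial growth factor gene, had 2.73 ± 0.552 and 4.70 ± 1.43 RPKM in adductor and 3.43 ± 0.881 and 2.53 ± 0.510 RPKM in gastrocnemius. The differences of effects were -1.03 ± 0.26 for Figf, -2.34 ± 0.63 for Igfn1, -1.16 ± 0.32 for Nnt, -0.68 ± 0.19 for Trib2 and 1.91 ± 0.55 for Mir27a. Mir27a, a microRNA precursor, reached at most 1.94 RPKM in any library.

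In this contrast limma called 0 genes, with 154 at an unadjusted p under 0.05, and with the replicate number as a block it called 0 with 470 unadjusted. Voom called 0 genes. In the second set alone limma called 1 gene, lower, and 0 in the first. Of the lists, 6 passed at the preset correlation. All 40 oxidative phosphorylation genes had a positive difference (median 0.29, adjusted p = 1.4e-09; within the sets 0.31 and 0.27), and this list, with a median of -0.29 in adductor, had 0.04 in gastrocnemius (adjusted p = 0.077), where it passed upward with terms for the set (34 of 40 positive, adjusted p = 1.2e-09) and within each set (medians 0.14 and 0.16), though not with an estimated correlation (adjusted p = 0.59 with terms for the set). A positive difference was also found in 13 of 14 fast-fibre genes (0.46, adjusted p = 3.7e-05; within the sets 0.42 and 0.56). Adipocyte markers had 0.71 (adjusted p = 2.6e-08; within the sets 0.78 and 0.26), glycolysis genes 0.35 (adjusted p = 1.0e-07; within the sets 0.45 and 0.28), lipogenic genes 0.29 (adjusted p = 0.00015; within the sets 0.35 and 0.06) and cholesterol genes -0.38 (adjusted p = 0.0017; within the sets -0.35 and -0.62). With an estimated correlation the adjusted p was 0.48 for the adipocyte and glycolysis lists and 0.66 for the other 4. Erythroid markers, lower in both muscles, had a difference of -0.69 (adjusted p = 0.32).

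Across the tested genes the diabetes effects of the muscles correlated with Pearson's r of 0.40 and Spearman's rho of 0.26, with a covariance of 0.0297. The contrasts share no library but may share animals, genes are not independent replicates, and 1 gene, Nnt, was called in both. With terms for the set r was 0.17, and it was 0.21 in the first set alone and 0.098 in the second set alone. The adductor effects of the first set correlated with those of the second at -0.0897, and the gastrocnemius effects at 0.284.

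The muscles themselves differed widely in control mice, a comparison that holds muscle identity and ischemia together. Genes of matrix and of regenerating muscle had the highest differences. Postn, the matrix protein periostin, rose from 17.8 ± 34.9 to 664 ± 339 RPKM, where control adductor 2 alone had 89.0 RPKM among the adductor libraries. Tmem8c, the myoblast fusion factor myomaker, rose from 2.44 ± 4.45 to 158 ± 70.3 RPKM, and Spp1, osteopontin, from 3.10 ± 4.84 to 204.5 ± 111 RPKM (SD, n = 6). Mest, Cthrc1 and C1qtnf3 rose by log2 differences of 6.18 ± 0.54, 6.11 ± 0.55 and 5.96 ± 0.57. The genes with the lowest values included Scn4b, a sodium channel subunit, which fell from 108 ± 18.1 to 9.82 ± 18.6 RPKM, the muscle-secreted peptide gene Ostn (31.7 ± 10.7 to 7.33 ± 17.2 RPKM) and the kinase gene Mylk4 (226 ± 58.7 to 32.7 ± 57.2 RPKM), followed by Plcd4, Tuba8 and Tspan8 at -3.85 ± 0.52, -3.81 ± 0.78 and -3.74 ± 0.59.

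For these 12 genes the adjusted p from limma ran from 9.9e-09 for Mest to 0.002 for Ostn, and all 6 gastrocnemius libraries lay outside the range of the adductor libraries except for Ostn, where 5 of 6 did. In all, 6730 genes were called higher and 1077 lower, and 4807 of them changed at least 2-fold. The median of all tested genes was itself 0.66 higher in the gastrocnemius on the log2 scale, and with median-of-ratios scaling, which removes such a shift, 3520 genes were higher and 3279 lower, and with quantile normalization 3158 were higher and 3503 lower. The within-set calls were 7347 higher and 594 lower in the first set and 6349 and 1512 in the second. On the median-of-ratios scale the log2 differences were 5.72 for Postn, 5.81 for Tmem8c, 5.55 for Spp1, -5.37 for Scn4b and -4.90 for Ostn.

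Every tested member of the matrix, cell cycle, interferon, tendon and inflammatory lists passed as higher, though only 10 of the 19 inflammatory genes were expressed enough to be tested. The 23 extracellular matrix genes had a median of 3.88 (camera adjusted p = 5.3e-08), with Timp1, an inhibitor of matrix proteases, going from 1.77 ± 1.18 to 108 ± 51.5 RPKM and Bgn, biglycan, from 38.1 ± 30.7 to 671 ± 290 RPKM (SD, n = 6). The 22 cell cycle genes had a median of 2.89 (adjusted p = 5.0e-06), with the mitotic cyclin Ccnb2 at 3.55 ± 0.35. The 19 interferon-stimulated genes had 1.88 (adjusted p = 0.00034), the 7 tendon and cartilage markers 3.80 (adjusted p = 0.00034) and the 10 inflammatory cytokines and chemokines 2.68 (adjusted p = 0.019), with the monocyte chemokine Ccl2 at 3.59 ± 0.58. Of 16 satellite cell and regeneration markers 14 rose (median 3.92, adjusted p = 2.6e-05), among them the perinatal myosin Myh8, from 9.10 ± 13.0 to 268 ± 38.0 RPKM, and the fetal acetylcholine receptor subunit Chrng, from 0.239 ± 0.456 to 29.7 ± 13.2 RPKM. Of 18 macrophage markers 17 rose (median 3.30, adjusted p = 0.00011), with the lysosomal protease Ctss going from 10.6 ± 10.0 to 236 ± 89.5 RPKM. Each of these 7 lists kept its direction with median-of-ratios scaling, and with an estimated correlation the adjusted p was 0.26 for the satellite cell and tendon lists, 0.50 for the matrix, cell cycle and macrophage lists and 0.52 for the interferon and inflammatory lists.

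Lists of energy metabolism and fast fibres were lower. Of 14 fast-fibre genes 8 fell (median -1.31, adjusted p = 1.6e-08), including the fast myosin heavy chain Myh4, at -2.19 ± 0.37, and the calcium pump Atp2a1, at -2.03 ± 0.37. Of 18 glycolysis and glycogen genes 12 fell and 1 rose (median -0.96, adjusted p = 1.9e-09), with glycogen phosphorylase Pygm at -2.05 ± 0.37 and Pgm1 at 2.01 ± 0.29. Pgm1 had only 2.39 to 8.42 RPKM in control gastrocnemius, against 292 to 1305 for Pygm. Its list entry accepted Pgm1 or Pgm2, and whether the symbol used is the main muscle form was not checked. Of 23 fatty acid oxidation genes 11 fell and 2 rose (median -0.57, adjusted p = 7.2e-07), the latter being Plin2, a lipid droplet coat protein, and Angptl4, a lipase inhibitor. Oxidative phosphorylation genes had a median of -0.34 with 3 of 40 called lower (adjusted p = 1.6e-08), and circadian clock genes -0.31 with 4 lower and 1 higher of 16 (adjusted p = 0.00034). With an estimated correlation the adjusted p was 0.50 for oxidative phosphorylation and 0.26 for the other 4. Adipocyte markers (median -0.34, adjusted p = 0.02), lipogenic genes (-0.01, adjusted p = 0.022), muscle atrophy genes (0.13, adjusted p = 0.0055) and antioxidant genes (0.28, adjusted p = 0.04) also lay below the other genes at the preset correlation, but not with median-of-ratios scaling (adjusted p = 0.17, 0.27, 0.11 and 0.08). Medians of the atrophy and antioxidant lists were positive while their tests pointed down, because the test compares them with all other genes. Their estimated-correlation adjusted p was 0.53 for the adipocyte and lipogenic, 0.26 for the atrophy and 0.50 for the antioxidant list.

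Several lists that did not pass still held called genes. Of 15 endothelial markers 8 rose, for example Pecam1 at 1.06 ± 0.15, with a list median of 0.71 (adjusted p = 0.81). On the median-of-ratios scale Pecam1 (0.28, limma adjusted p = 0.089), Tie1 (0.34, 0.052) and Robo4 (0.01, 0.95) lost their calls, while Emcn kept its call (0.75, 0.017). Of 19 angiogenic ligands and receptors 13 rose and 2 fell (median 0.75, adjusted p = 0.70), with the chemokine receptor Cxcr4 at 3.38 ± 0.32 and Apln, apelin, at 2.85 ± 0.32, while Vegfa fell by 1.19 ± 0.30, from 22.2 ± 7.45 to 9.56 ± 3.56 RPKM, with all 6 gastrocnemius libraries below every adductor library. Smooth muscle and pericyte markers had 9 higher and 3 lower of 13 (median 1.21, adjusted p = 0.94). Of 17 hypoxia-induced genes 8 rose and 5 fell (median 0.37), but the test against all other genes pointed down (adjusted p = 0.066; 0.049, also down, with the replicate number as a block). Alternative macrophage activation genes had 6 higher and 1 lower of 11 (median 1.49, adjusted p = 0.81), the one that fell being Retnla, from 35.1 ± 13.2 to 5.42 ± 3.86 RPKM. The slow-fibre list had 6 higher and 3 lower of 10 (1.55, adjusted p = 0.94), with Tnni1, slow troponin I, at 3.62 ± 0.32. Fibroblast markers had 9 of 10 higher (1.49, adjusted p = 0.089), cholesterol genes 11 higher and 1 lower of 17 (1.04, adjusted p = 0.54), insulin signalling genes 10 higher and 3 lower of 20 (0.55, adjusted p = 0.73), endoplasmic reticulum stress genes 11 higher and 1 lower of 15 (1.61, adjusted p = 0.40), and immediate early genes 10 higher and 1 lower of 14 (1.39, adjusted p = 0.54). Markers of neutrophils (0.97, adjusted p = 0.94), lymphocytes (1.77, adjusted p = 0.50), Schwann cells (0.38, adjusted p = 0.81), keratinocytes (0.89, adjusted p = 0.54) and erythroid cells (-0.05, adjusted p = 0.089) did not pass. Igf2 rose from 26.8 ± 45.6 to 468 ± 96.2 RPKM, Slc2a4 fell by 1.96 ± 0.39 and Ucp3 fell by 1.83 ± 0.55. Flt1 (-0.65 ± 0.32) and Pdk4 (-1.49 ± 0.71) did not pass, though both did with median-of-ratios scaling (-1.37, adjusted p = 0.00058, and -2.28, adjusted p = 0.015), with quantile normalization, with terms for the set (adjusted p = 0.0032 and 0.029) and with the replicate number as a block. Not passing either were Kdr (0.20 ± 0.42) and Adipoq (0.04 ± 0.58), whose signs turned with median-of-ratios scaling (-0.51 and -0.72) and with quantile normalization.

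In diabetic mice the same muscle comparison gave 5958 genes higher and 1093 lower in the gastrocnemius, with a median shift of 0.55 over all genes. With median-of-ratios scaling 3396 were higher and 3248 lower, and with quantile normalization 3035 and 3562. The smallest p-values belonged to Mmp13, a collagenase (4.82 ± 0.30), Il18bp, an interleukin-18 antagonist (3.75 ± 0.24), the homeobox genes En1 (2.76 ± 0.18) and Six2 (2.58 ± 0.17), and Tnmd, a tendon glycoprotein (3.74 ± 0.25), all with a limma adjusted p between 2.6e-10 and 3.3e-10. Matrix, cell cycle and interferon lists again had every tested member higher (medians 3.47, 2.69 and 1.66). In this comparison 17 lists passed at the preset correlation and 0 with an estimated correlation. The within-set calls were 7101 higher and 926 lower in the first set and 4363 and 1621 in the second. Log2 differences of the muscle contrasts in control and diabetic mice correlated at 0.960 across genes, and 5718 genes were called higher in both (3238 expected from independent lists) and 880 lower in both (95.1 expected). The contrasts share no library.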

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

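The tests of depth, of the share of repeated sequence in the genes that fell most, of within-set differences and shared reads of Nnt, and of swapped labels were chosen only after the result was seen, as was the bound by which the median of genes with shared sequence was judged too imprecise to decide.

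Some libraries stood apart from the other 5 of their group in the level of a named gene, by the ratio of the gap to the whole range. There were 19 such cases in 116 combinations of 29 genes and 4 groups, where chance gives about 1 in 20, and genes are not independent. Control adductor 2 was the highest of its group in 7 genes, with 119.8 RPKM of Igf2, 89.0 of Postn, 23.0 of Mest, 12.9 of Spp1, 11.5 of Tmem8c, 8.78 of C1qtnf3 and 3.91 of Cthrc1. Control gastrocnemius 3 was the lowest in Spp1 (34.1 RPKM), Tmem8c (30.6) and Clec4d (1.001) and the highest in Mylk4 (149.5), Scn4b (47.7) and Ostn (42.4). Diabetic gastrocnemius 2 was the lowest in Tmem8c (39.8) and Cthrc1 (12.3), and diabetic adductor 1 the lowest in Mylk4 (78.7) and Nnt (18.0). Nnt was lowest in control gastrocnemius 5 (4.72) and Snapc1 highest in control adductor 5 (3.37).

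By the camera test of the difference of effects at the preset correlation 6 gene lists passed, while limma called 0 genes. Splits of the libraries were not counted for these lists, so chance is not excluded. The median differences, gastrocnemius minus adductor, were 0.71 for adipocyte markers, 0.46 for fast-fibre genes, 0.35 for glycolysis genes, 0.29 for oxidative phosphorylation genes, 0.29 for lipogenic genes and -0.38 for cholesterol genes. None of the 6 passed with an estimated correlation.

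The first pattern is the split of the libraries in sets by Gapdh. Lower depth of the second set argues poorly for it, since 57 genes of at least 100 RPKM in the first set fell at least 8-fold, and GC content does too, since all 5137 tested genes in the interquartile GC range of the 138 falling genes had a median of only -0.13. Reads matching several genomic places may have been handled differently in the sets: the falling genes had a median of 34.8% of their 31-base words in another gene, against 0.111% of all tested genes. Among genes of at least 100 RPKM in the first set, the falling genes had a median of 40.2% and the 363 others 1.19%. However, genes with at least 50% shared words had a median only 0.43 below that of genes sharing none (-0.43). The interquartile range of the former was wide, -1.59 to 0.39. By the bounds written in advance (a drop of 1 for, under 0.5 against) the difference of medians counts against shared sequence in general. It is called open only because its bootstrap interval, -0.56 to -0.31, holds values beyond 0.5. A difference of sequencing instrument between the sets was not tested. No biological explanation was tested, as both sets hold both mouse groups and both muscles.

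The second pattern is the higher Nnt in the diabetic mice. Unequal shares of the sets do not account for it, since the smaller of the within-set log2 differences was 2.35 in adductor and 1.32 in gastrocnemius, and neither do reads of a related gene, since 0% of its 31-base words lay in another gene. Mice of the C57BL/6J substrain are known to carry a deletion within Nnt, the labels give only C57BL/6, and values summed over all exons cannot show a deletion, so a difference of substrain could be the source and was not tested. An effect of diabetes itself stays open as well, and the data do not tell these apart.

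The third pattern is the place of control gastrocnemius 3 and diabetic gastrocnemius 2 between the muscles. A swap with adductor libraries is argued against, since 0 adductor libraries correlated better with the gastrocnemius medians than with those of adductor. A mixture with adductor-like tissue in 1 proportion, which would lower all gastrocnemius genes alike, could not be decided: over 47 genes the log2 ratios to the other libraries had an interquartile range of 0.880 in the control and 1.08 in the diabetic library, and other libraries had 0.50 to 1.04. Less severe ischemia in these animals is a biological explanation that the data do not test.

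Other groupings of the same libraries were fitted for each count. In the adductor 4 of 100 splits, the real one included, gave as many genes as the real 4. This is below the bound of 5 in 100 set in advance. However, 100 draws cannot tell 4 from 5, so chance is not firmly excluded. Another split gave 1567 genes, with 5 libraries of the second set on 1 side and 0 on the other. This points to the sets as a structure of the samples. Among splits drawn within the sets, with terms for the set, 3 of 100 gave as many as the real 5, and the highest other gave 61. In the gastrocnemius 14 of 100 splits gave as many genes as the real 1 (highest 5639, again 5 libraries of the second set against 0), so chance is not excluded. For the gene lists 34 of 100 splits gave as many as the 10 of the adductor (median of the others 8, highest 13). In gastrocnemius 19 of 100 gave as many as the 14 (median of the others 9, highest 20). Chance is not excluded for either count. Those splits ignore the sets. Splits were therefore also drawn within the sets and fitted with terms for them, a test added after the result was seen. Of these, 5 of 100 gave as many as the real 14 lists in adductor (median of the others 8, highest 19). In gastrocnemius 21 of 100 gave as many as the real 13 (median of the others 9, highest 16), so chance is not excluded there either. A typical other split thus also called several lists at the preset correlation. For the difference of effects 100 of 100 splits gave as many as the real 0 genes (highest 1), which any split must and which tests nothing. Between the muscles the numbers were taken as pairs, which the labels do not state. There 1 of 32 splits, the real one, gave as many as 7807 genes in control mice (highest other 5807). In diabetic mice 1 of 32 gave as many as 7051 (highest other 5384). These shares are the smallest that 32 splits allow and argue against chance. The other splits exchange muscles within some of the assumed pairs.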

How the results depend on the processing

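Set terms, within-set fits, voom, sex-linked terms and the omission of control gastrocnemius 3 and diabetic gastrocnemius 2 were chosen only after the data were seen. The causes of the changes below were not tested, except that a filter of 5 RPKM tests fewer genes and within-set fits use fewer libraries.

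The adductor count of 4 became 1 when only the groups compared were fitted, 79 with array weights (a fit that stopped before convergence), 10 with set and sex-linked terms, 1 in the first and 14 in the second set, 8 with set terms and median-of-ratios scaling, and 15 with set terms and the pair of libraries omitted. Leaving out 1 library gave 1 to 4 genes. Serpina3n lost its call without control adductor 3, 5 or 6 or diabetic adductor 1, 2, 4 or 5 (highest adjusted p 0.16). Apod lost it without control adductor 2, 3, 5 or 6, control gastrocnemius 5 or 6, diabetic adductor 1, 2, 3, 4 or 5 or diabetic gastrocnemius 2 (0.17). Abcg1 kept it only without control adductor 2, control gastrocnemius 1 or 3, diabetic adductor 1 or diabetic gastrocnemius 3, 4 or 6 (highest 0.19).

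The gastrocnemius count of 1 became 2 with a pseudocount of 1, 4 without a filter, 2 with quantile normalization, 0 when only the groups compared were fitted, 13 with array weights (not converged), 0 with set terms, 0 in the first and 27 in the second set, 2 with set terms and median-of-ratios scaling, and 24 with set terms and the pair omitted. Leaving out 1 library gave 0 to 3 genes, 3 without control gastrocnemius 3. Nnt kept its call there only without control adductor 4, control gastrocnemius 3, diabetic adductor 1, 3 or 6 or diabetic gastrocnemius 1 or 5 (highest adjusted p 0.16). The difference of effects, with 0 genes, gave 1 in the second set and 1 with set terms and the pair omitted, and 0 to 0 with 1 library left out. With a filter of 5 RPKM the muscle counts were 4962 in control and 4501 in diabetic mice; leaving out 1 library gave 7233 to 8011 and 6531 to 7242. The correlation of the effects was 0.17 with set terms, 0.21 in the first and 0.098 in the second set, and 0.20 to 0.51 with 1 library left out.

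With the replicate number as a block the gastrocnemius count was 0, with an adjusted p of 0.056 for Nnt. Same-numbered control and diabetic samples share their sex-linked pattern and, except number 4, their set. For the muscle contrasts, with the numbers taken as pairs, the block gave 9168 genes in control and 8498 in diabetic mice and 0 for the difference of effects. The hypoxia list of control mice then passed downward against other genes (adjusted p = 0.049) despite a positive median, and the fibroblast and inflammatory lists of diabetic mice no longer passed (adjusted p = 0.052 and 0.051). Under the block Abcg1 (adjusted p = 0.25) and Apod (0.054) lost their calls in adductor, Flt1 (0.0016) and Pdk4 (0.0069) gained theirs between the muscles of control mice, and no other named gene or list of the muscle contrasts changed its call. Between the mouse groups the block removed the calls of the gastrocnemius cell cycle (0.052), glycolysis (0.052), neutrophil (0.084) and endoplasmic reticulum (0.061) lists and of the adductor fast-fibre list (0.060), and added the adductor adipocyte list (0.025). In 6 pairs of 12 between the muscles a sample correlated best with its own number.

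With an estimated correlation the lists called were 0 in the adductor (10 preset), 1 in the gastrocnemius (14), 0 for the difference of effects (6), 0 between muscles in control (16) and 0 in diabetic mice (17). With set terms as well they were 0, 0, 0, 0 and 0. In the first set alone the difference of effects gave 15.

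Of 2053 comparisons of single genes with an alternative, 1997 kept direction and call, 23 lost and 19 gained the call, and 14 turned sign. With set terms these were Flt1 at -0.0197 in adductor and -0.0174 in gastrocnemius, Pdk4 at 0.16 and Ucp3 at 0.0177 in gastrocnemius. With quantile normalization Igf2 was -0.0696 and Pdk4 0.00538 in gastrocnemius, and between the muscles of control mice Robo4 was -0.0602, Pparg -0.15, S100b -0.27, Sfn -0.0126, Kdr -0.61 and Adipoq -0.55. With median-of-ratios scaling Kdr was -0.51 and Adipoq -0.72. Depth limits low genes: 3 reads of a 1 kb transcript are 0.421 RPKM in the shallowest library.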

Other observations

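The search for genes that differ in both muscles was chosen only after the result was seen; the test of liver X receptor targets was set before their values were examined, but after Abcg1, Srebf1 and Apoc1 had drawn attention to them.

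With terms for the set, 55 genes had an unadjusted p under 0.05 and the same sign in both muscles; 35 were higher and 20 lower in diabetic mice. Some are near-identical entries, such as the globin genes, and the muscles may share animals, so no number expected by chance is given. The genes below were chosen after their values were seen. Srebf1, the lipogenic transcription factor, had log2 differences of 1.27 in adductor (adjusted p = 0.028) and 0.69 in gastrocnemius. Nnat, neuronatin, had 1.96 and 1.64, and the centrosomal gene Lrrcc1 had -0.81 and -0.81. Lyve1, a marker of lymphatic vessels and of some resident macrophages, had -0.64 and -1.04, and Cyp2e1 had -1.51 and -0.93. Apart from Srebf1 in the adductor, these did not pass over all genes.

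Higher values of Abcg1 and Srebf1 in both diabetic muscles and of Apoc1 in gastrocnemius came with lower values of cholesterol synthesis genes in gastrocnemius, which may reflect higher activity of liver X receptors, the nuclear receptors that respond to sterols. If so, 10 other target genes were to have a median of at least 0.3 and an unadjusted camera p under 0.05. With terms for the set their median was 0.39 in adductor, with 9 of 10 positive (p = 1.1e-05; 0.041 with an estimated correlation), and 0.35 in gastrocnemius, with 10 of 10 positive (p = 6.2e-11; 0.0042). The cholesterol efflux transporter Abca1 had 0.90 ± 0.33 and 0.72 ± 0.33, and Lpcat3, a phospholipid remodelling enzyme, 0.81 ± 0.19 and 0.30 ± 0.19. These medians met the prediction in both muscles. Within the sets the adductor medians were 0.08 and 0.67, and macrophage markers there moved alike (-0.36 and 0.64), as did Apoe (0.02 and 1.16) and Pltp (-0.18 and 1.40), so a larger share of macrophages could also raise the targets in adductor. In gastrocnemius the medians were 0.48 and 0.31, against 0.17 and -0.09 for macrophage markers. Adipocyte markers had 0.52 and 0.45 there, so these values do not set the targets apart from a change in tissue make-up. In adductor, with terms for the set, camera placed lipogenic genes lower (median -0.06, adjusted p = 0.024), although their member Srebf1 was higher. Their within-set medians were -0.31 and 0.18. Cholesterol genes were also lower there (median -0.07, adjusted p = 0.029). Both lists had 0.57 with an estimated correlation.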
